A study of Mus musculus with 15 samples.

How the data were processed

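Total RNA of jejunal epithelium scraped off the muscle wall was measured on 15 bead arrays, 1 per mouse, in 4 genotype groups. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with DNase and labelled in 1 colour with a TotalPrep-96 kit. The deposited values are log2 expression values for 25695 probes, made comparable between arrays by the authors. Their normalization method is not given in the sources used here. Array means lay close together while the distributions differed, so the values had not been quantile normalized. They were used as deposited, with 0 missing values and 0 pairs of identical arrays. A few values lay below 0. No detection p-values were used, so values near the array medians, 5.59 to 5.90, are close to background. Where a group mean was no higher than 5.90, background can hide part of a difference from it, so its size is uncertain. The number of arrays limits the precision.

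The sample labels gave each array's group and replicate number. Labels describe cohorts of mice, so replicates are separate mice. Of the probes, 23976 carried 1 gene symbol, 1719 were unnamed here and 0 carried several. There were 16592 genes, 4776 of them with more than 1 probe, and the probe with the highest mean over the 15 arrays stood for its gene in named genes and lists. Counts of changed probes include unnamed probes.

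One model with a mean per genotype was fitted to all arrays with limma 3.58.1 in R 4.3.3, with 11 residual degrees of freedom, and each of 6 contrasts was tested with moderated statistics at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were each deficient group against control, Brg1-Apc deficient against Apc deficient and against Brg1 deficient, and the interaction. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All tests were two-sided.

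There were 35 gene lists with 741 genes, 639 of them measured. They covered Wnt target genes, Wnt pathway components and feedback inhibitors, crypt base stem cell, reserve stem cell, Paneth, goblet, enteroendocrine and tuft cell markers, enterocyte digestion and nutrient transport, enterocyte lipid absorption, brush border structure, bile acid and xenobiotic metabolism and cholesterol synthesis. Others were DNA replication and G1/S, G2/M and mitosis, ribosome biogenesis, the Notch pathway, SWI/SNF subunits, p53 targets, interferon-stimulated genes and antigen presentation, epithelial defence and acute phase genes, immediate early and heat shock genes, the unfolded protein response and glycolysis. Lists for other cell types held markers of T cells and intraepithelial lymphocytes, B and plasma cells, macrophages and dendritic cells, mast cells, fibroblasts and matrix, smooth muscle, endothelium, enteric neurons and glia, pancreatic acinar cells, red blood cells and adipocytes. Each list was tested in each contrast with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, which gave 210 tests, and again with an estimated correlation and with fry. Of the 29 measured Wnt targets 12 are on another list too, and of the 19 stem cell markers 10 are.

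The named genes were chosen by a rule fixed before the data were examined, among probes with 1 symbol. It took Smarca4 and Apc in every group. In Brg1 deficient against control, Apc deficient against control and Brg1-Apc deficient against Apc deficient, it took the 5 largest rises and falls past the test whose arrays did not overlap between the groups. In these comparisons it also took the 3 members with the smallest p of each list past the test, or 2 where a comparison would pass 30 genes, and 2 of the Wnt, stem cell, Paneth, goblet, enteroendocrine, tuft and enterocyte digestion lists in any case. For the interaction it took the 5 largest values on each side and 2 members of the Wnt and stem cell lists. For the other 2 comparisons it took the 3 largest rises and falls. Other members are given as values where their list is described.

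Across genes, slopes were computed as the covariance over the variance of the horizontal values less their mean squared standard error, with a jackknife SE over arrays. The alternatives were slide as a block, the replicate number as a block, each slide alone, quantile normalization, centring each array on its median, only probes above the median level, only the 2 groups compared, a trended and robust prior, array weights, 1 probe per gene or the most variable one, and leaving out each array. A further one, leaving out Brg1 deficient replicate 4 and Brg1-Apc deficient replicate 2, was chosen after seeing the data. Single arrays were compared with their group by Dixon's test, with a critical value of 0.829 for 4 arrays.

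The model was tested in 5 simulations with 200 of 25695 probes changed. Real comparisons had up to 3390, so recovery and false calls need not carry over to them. At true log2 differences of 1 and 2, recovery of the 200 was 6.4% and 77.2% in the interaction. It was 42.4% and 96.8% for Brg1 deficient against control and 27.8% and 95.4% for Apc deficient against control. For Brg1-Apc deficient mice it was 33.4% and 95.8% against Apc deficient, 45% and 97.4% against control and 46.4% and 97.2% against Brg1 deficient mice. False calls made up 4% to 6.32% of the calls.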

Results

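Gene expression was measured in epithelium scraped from the jejunum, the middle stretch of the small intestine, of 15 mice. The mice of the deficient groups carried VillinCreERT2, a Cre recombinase made in gut epithelium and switched on by tamoxifen, together with alleles of Brg1, of Apc or of both that Cre can inactivate. Brg1 is the product of Smarca4, an ATPase of the SWI/SNF complexes that move nucleosomes. Apc belongs to the complex that marks beta-catenin for destruction, so that its loss turns on the Wnt pathway. There were 4 control mice without Cre, 4 Brg1 deficient, 3 Apc deficient and 4 Brg1-Apc deficient mice. Each received 4 daily tamoxifen injections of 80 mg/kg, and tissue was taken on day 4 after induction, a time at which the authors had checked the loss of Brg1 in the epithelium by immunohistochemistry. The comparisons ask what the loss of Brg1 does where Wnt signalling is normal and where it is aberrant. Because the controls carried no Cre, every comparison against control includes whatever induced Cre itself does, and so does the interaction, in which that effect does not cancel. Brg1-Apc deficient against Apc deficient and against Brg1 deficient mice are comparisons between Cre-positive groups.

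Array medians lay between 5.59 and 5.90, and 16.1% to 23.1% of the probes of an array were above 8. Arrays of the same group correlated at r of 0.871 to 0.977 across probes, and arrays of different groups at 0.806 to 0.961. The first principal component held 32.2% of the variance and placed the 3 Apc deficient arrays between -95.2 and -60.1 and all 12 others at -8.60 or higher. Brg1 deficient replicate 4 stood apart, with an interquartile range of 1.23 against 1.89 to 2.56 on the other 14 arrays and the lowest mean correlation with its own group, 0.893. RNA of other tissues was seen on single control arrays. Pancreatic acinar markers averaged 10.39 on control replicate 4 and 6.49 or less on each of the other 14 arrays. Smooth muscle markers averaged 9.33 on control replicate 1 and 6.39 to 7.95 elsewhere. Replicates 1 and 2 of each group were on slide 1 and the others on slide 2, with a single Apc deficient array on slide 2. None of the 8 positions on a slide held arrays of more than 1 genotype, so that position and genotype cannot be told apart.

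Smarca4 followed the labels in every group. Its probe averaged 7.55 ± 0.17 (SD, n = 4) in control, 6.20 ± 0.14 (n = 4) in Brg1 deficient, 8.15 ± 0.26 (n = 3) in Apc deficient and 6.08 ± 0.06 (n = 4) in Brg1-Apc deficient mice. It fell by 1.36 (SE 0.17) on the log2 scale in Brg1 deficient against control mice (limma adjusted p = 0.000215) and by 2.07 (SE 0.18) in Brg1-Apc deficient against Apc deficient mice (adjusted p = 7.28e-06). Brg1-Apc deficient and Brg1 deficient mice differed by -0.11 (SE 0.17, adjusted p = 0.825). Smarca4 was 0.60 (SE 0.18) higher in Apc deficient than in control mice (adjusted p = 0.0339). This last call ended without Apc deficient replicate 1 or 2 or control replicate 2, 3 or 4 (adjusted p from 0.0526 to 0.166). The 2 Apc probes passed the test in no comparison, with a lowest adjusted p of 0.146. The brighter probe averaged 6.99 ± 0.51 in control, 6.49 ± 0.95 in Brg1 deficient, 7.07 ± 0.84 in Apc deficient and 6.03 ± 0.49 in Brg1-Apc deficient mice. Where these probes lie relative to the deleted part of Apc is not given in the sources used here, so they check nothing about the labels.

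**Figure D1:**
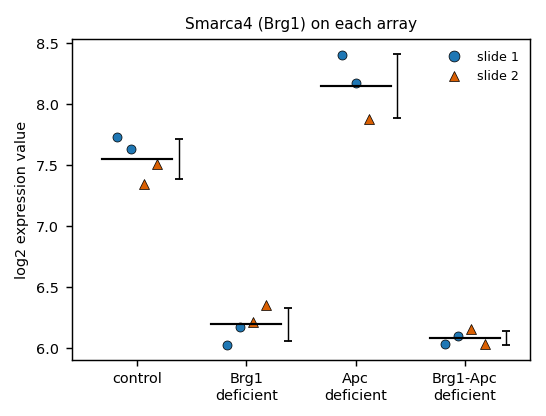
Log2 value of the Smarca4 probe (vertical axis) on each array by group, with circles for slide 1, triangles for slide 2, a horizontal line at the group mean and brackets of ± 1 SD. All 8 arrays of the groups without Brg1 lie below all 7 arrays with Brg1.

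With loss of Brg1 and normal Wnt signalling, 6 lists were lower by camera, those of crypt base stem cell markers, Wnt targets, the Notch pathway, G1/S, G2/M and ribosome biogenesis, and 0 of the 6 passed with an estimated correlation. Olfm4, a marker of stem cells at the base of the crypt, fell from 9.87 ± 0.59 in control to 6.29 ± 0.89 in Brg1 deficient mice (SD, n = 4 each), a 12-fold drop (limma adjusted p = 0.000338). Nrarp, a Notch target that feeds back on the pathway, fell by 2.80 (SE 0.26, adjusted p = 2.31e-05), and Sp5, a direct Wnt target, by 1.62 (SE 0.24, adjusted p = 0.00105). Among genes past the test whose arrays did not overlap between the groups, the largest rises were in Hapln4 at 4.21 (SE 0.33, adjusted p = 8.66e-06), and Slc2a6 at 3.40 (SE 0.40, adjusted p = 0.000142). The largest falls were in St3gal4 at -4.96 (SE 0.55, adjusted p = 8.86e-05), and Cyp3a25 at -4.76 (SE 0.62, adjusted p = 0.000385). Next came 1700016K19Rik at 2.47, Gpr151 at 2.42, and Gamt at 2.22. On the other side were Nat8 at -4.15, Adh1 at -4.06, and Cyp3a11 at -3.81, with adjusted p from 4.15e-05 to 0.0108. The control means of Hapln4 and 1700016K19Rik were at background, no higher than 5.90. So were the Brg1 deficient means of St3gal4, Cyp3a25 and Cyp3a11, and the size of all these differences is uncertain.

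Among the lists fixed beforehand, the 19 measured crypt base stem cell markers shifted by a mean of -0.71 (camera adjusted p = 0.00084; adjusted p = 0.389 with an estimated correlation). Of these 4 fell, 0 rose and 15 did not pass the test, and 7 fell when adjusted over the list alone. Besides Olfm4 these included Slc12a2 at -1.99 (SE 0.34, adjusted p = 0.00343; 1 of its 3 other probes, near background, had the opposite sign), and Cdca7 at -2.06. Of the 29 Wnt target genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone), with a mean of -0.36 (adjusted p = 0.0422; adjusted p = 0.389 with an estimated correlation). They were Sp5, Tiam1 at -1.48 (adjusted p = 0.00274), Ccnd1 at -2.10, Cdca7 and Cd44. The lists of Wnt targets and of stem cell markers share 9 measured genes, Cdca7 and Cd44 among them. Of 23 Notch pathway genes, 5 fell and 0 rose, with a mean of -0.45 (adjusted p = 0.037; adjusted p = 0.389 with an estimated correlation); adjusted over the list alone, 5 fell and 1 rose. The 5 were Nrarp, Olfm4, the ligand Dll1 at -1.32, and Hes1 at -1.40 and Hes6 at -0.85.

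Of 26 genes of DNA replication and the G1/S step, 7 fell and 0 rose (14 and 0 adjusted over the list alone), with a mean of -0.71 (camera adjusted p = 9.89e-08; adjusted p = 0.425 with an estimated correlation). Mcm10 and Mcm4 were at -1.28 (SE 0.25, adjusted p = 0.00909) and -1.39 (SE 0.28, adjusted p = 0.0112). The other 2 Mcm4 probes, which did not pass the test, had the opposite sign. Of 27 genes of G2/M and mitosis, 4 fell and 0 rose (12 and 0 adjusted over the list alone), with a mean of -0.58 (adjusted p = 0.000336; adjusted p = 0.638 with an estimated correlation), Birc5 at -1.65 and Prc1 at -1.29 among them. The ribosome biogenesis list shifted by -0.46 (adjusted p = 0.003; adjusted p = 0.659 with an estimated correlation), with 0 of 24 genes past the test in limma and 5 falling when adjusted over the list alone. Gnl3 was at -1.15 (adjusted p = 0.0517) and Fbl at -1.21 (adjusted p = 0.09).

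Markers of the differentiated cell types moved less evenly, and none of their lists passed the test. Of the goblet cell markers Guca2a rose by 1.13 (SE 0.22, adjusted p = 0.0075) and Klk1 fell by 1.45 (SE 0.29, adjusted p = 0.0111), with a list mean of -0.17 (camera adjusted p = 0.453). Paneth cell markers averaged -0.74 (adjusted p = 0.109), with Itln1 at -1.42 (adjusted p = 0.113) and Sox9 at -0.76 (adjusted p = 0.183). Enteroendocrine markers averaged -0.14 (adjusted p = 0.442), Isl1 being at -0.53 and Scg2 at -0.50, and tuft cell markers -0.12 (adjusted p = 0.442), with Avil at -0.67 and Alox5ap at -0.92 (adjusted p = 0.0403). The Alox5ap call ended without any 1 control array, Brg1 deficient replicate 1, 2 or 3, Apc deficient replicate 1 or Brg1-Apc deficient replicate 3 (adjusted p from 0.0531 to 0.122). The list of enterocyte digestion and nutrient transport averaged -0.40 (adjusted p = 0.18), with a fall in 1 of 22 genes, the trehalase Treh, at -3.07 (SE 0.61, adjusted p = 0.00999). The peptide transporter Slc15a1 was at -1.55 (adjusted p = 0.0572). Lipid absorption averaged -0.36 (0.0878), brush border structure -0.41 (0.276), reserve stem cell markers -0.10 (0.846) and cholesterol synthesis -0.34 (0.218), with the adjusted p in brackets. In bile acid and xenobiotic metabolism the members went both ways, with 7 of 32 falling, the Cyp3a genes and Nqo1 at -1.99 among them. The 3 that rose were the bile acid receptor gene Nr1h4 at 1.51, Gsta1 at 1.44 and Slc51b at 1.06 (list mean -0.59, adjusted p = 0.109). The 4 genes that fell in the list of interferon-stimulated genes and antigen presentation all belong to MHC class II. They were its master regulator Ciita at -1.82, H2-Aa at -1.45, H2-Eb1 at -1.34 and Cd74 at -1.03 (list mean -0.30, adjusted p = 0.0559).

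The remaining pathway lists did not pass the test either. Their means and adjusted p were -0.11 (0.423) for Wnt pathway components, -0.21 (0.276) for the other SWI/SNF subunits, -0.05 (0.975) for p53 targets, -0.11 (0.903) for epithelial defence. They were 0.08 (0.442) for immediate early and heat shock genes, -0.18 (0.805) for the unfolded protein response and 0.00 (0.461) for glycolysis. Markers of other cell types that a scrape can hold averaged -0.06 (0.85) for T cells and intraepithelial lymphocytes, 0.10 (0.423) for B and plasma cells. They averaged -0.10 (0.975) for macrophages and dendritic cells, 0.12 (0.423) for mast cells and -0.24 (0.378) for fibroblasts. They averaged -0.64 (0.109) for smooth muscle, -0.43 (0.109) for endothelium, 0.18 (0.276) for neurons and glia, -0.94 (0.071) for acinar cells, 0.21 (0.442) for red cells and 0.22 (0.276) for adipocytes. Smooth muscle was at -0.16 without control replicate 1 and at -1.01, past the test (0.00599), without control replicate 3, and acinar cells were at 0.13 without control replicate 4 and at -1.33, past the test (0.00234), without control replicate 1. The mean, the median and the test differed in sign for the p53, defence, macrophage, glycolysis, brush border, unfolded protein and reserve stem cell lists.

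In all, 721 probes changed by limma, 176 higher and 545 lower in Brg1 deficient mice, and 533 of them by more than 2-fold. Quantile scaling of the arrays gave a more even split, 293 higher and 308 lower among 601 probes. With slide as a block 840 probes changed, against 160 within slide 1 and 60 within slide 2. The count was 361 without control replicate 1, 431 without control replicate 2 and 432 without control replicate 4. It was 424 without Brg1 deficient replicate 3 and 1143 without Brg1 deficient replicate 1. The means of the 6 lists that passed the test moved by 0.00 at most with slide as a block. Within slide 1 and slide 2 they were -0.29 and -0.43 for Wnt targets, -0.62 and -0.80 for stem cell markers, -0.39 and -1.03 for G1/S. The values were -0.50 and -0.66 for G2/M, -0.27 and -0.65 for ribosome biogenesis and -0.46 and -0.45 for the Notch pathway. The Wnt call did not hold within slide 1 (adjusted p = 0.0594), without Apc deficient replicate 2 (0.0561) or without Brg1 deficient replicate 3 (0.0688). The call of ribosome biogenesis did not hold within slide 1 (0.0505), and that of the Notch pathway held neither within slide 2 (0.0702) nor without Brg1 deficient replicate 1 (0.123).

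**Figure D2:**
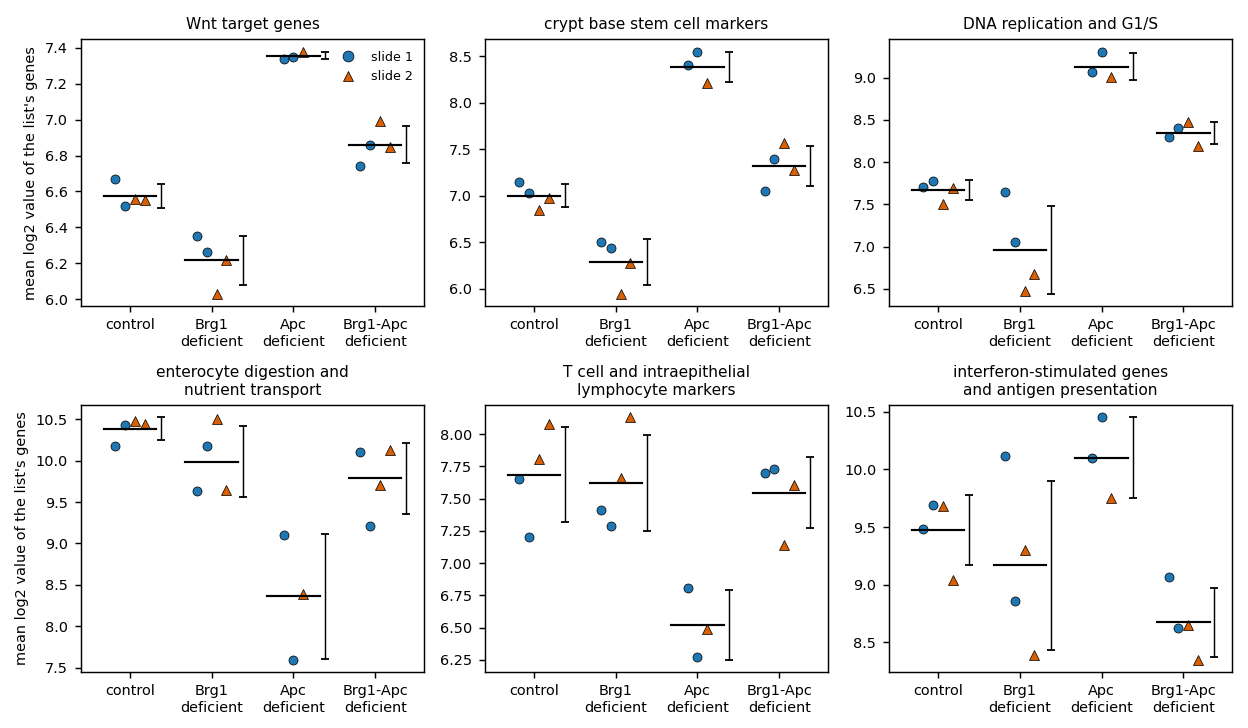
Mean log2 value of 6 gene lists (vertical axes) on each array by group, with circles for slide 1, triangles for slide 2, a line at the group mean and brackets of ± 1 SD. Against control, crypt base stem cell markers shifted by -0.71 in Brg1 deficient, 1.38 in Apc deficient and 0.32 in Brg1-Apc deficient mice.

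Loss of Apc changed the epithelium more widely. By camera, lists of Wnt targets, stem cell markers, cell division and ribosome biogenesis were higher and those of the absorptive enterocyte and of intraepithelial lymphocytes lower, and 2 of 15 lists, Wnt targets and stem cell markers, passed with an estimated correlation. Lgr5, the receptor that marks crypt base stem cells, rose by 1.76 (adjusted p = 0.000195) and Notum, a secreted Wnt inhibitor, by 1.55. The brush border peptidase Mme fell from 11.45 ± 0.28 (SD, n = 4) to 6.98 ± 1.30 (n = 3), 22.3-fold (adjusted p = 9.83e-05). The largest rises were in Defa31 at 5.47 (SE 0.87, adjusted p = 4e-04), and in Atg9b at 4.79 (SE 0.26, adjusted p = 3.4e-08). They were followed by Msx1 at 4.47, Rgcc at 4.34 and Krt23 at 4.15. The largest falls were in Dnase1 at -5.40 (SE 0.83, 42.3-fold, adjusted p = 0.000325). Next were Enpp7 at -4.60, Slc7a8 at -4.53, Naaladl1 at -4.50 and Mme at -4.48. These genes were chosen in the same way, and their adjusted p ran up to 4e-04. Defa31, Atg9b and Msx1 were at background in control mice, as were Tnfrsf19, Mex3a and Sox9, so the size of their rises is uncertain.

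Of 29 Wnt target genes, 14 rose and 1 fell (16 and 2 adjusted over the list alone), with a mean of 0.79 (camera adjusted p = 4.91e-07; adjusted p = 0.0186 with an estimated correlation). Tnfrsf19 rose by 2.54 (SE 0.26, adjusted p = 8.53e-06), Sp5 by 2.31 (SE 0.26, adjusted p = 2.26e-05) and Cd44 by 2.33 (SE 0.26, adjusted p = 2.53e-05), while Tgfbi fell by 2.81. Of 19 stem cell markers, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a mean of 1.38 (adjusted p = 8.33e-10; adjusted p = 0.0207 with an estimated correlation). Reserve stem cell markers shifted by 0.87 (adjusted p = 0.0288; adjusted p = 0.231 with an estimated correlation), with 2 of 6 genes rising, Lrig1 by 1.84 and Mex3a by 1.02 (SE 0.20, adjusted p = 0.00232), whose other probe had the opposite sign. Of 26 G1/S genes, 21 rose and 0 fell (24 and 0 adjusted over the list alone; mean 1.46, adjusted p = 1.36e-16; adjusted p = 0.0549 with an estimated correlation). Mcm2 was at 2.17 and Rrm2 at 1.80. Of 27 G2/M genes, 11 rose and 0 fell (15 and 0 adjusted over the list alone; mean 0.81, adjusted p = 8.15e-06; adjusted p = 0.217 with an estimated correlation). Bub1b was at 1.54 and Ndc80 at 1.24. Of 24 ribosome biogenesis genes, 17 rose and 0 fell (18 and 0 adjusted over the list alone; mean 1.26, adjusted p = 1.45e-11; adjusted p = 0.0503 with an estimated correlation). Gar1 was at 2.04 and nucleolin, Ncl, at 1.77.

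On the absorptive side, 18 of 22 genes of enterocyte digestion and transport fell and 0 rose (18 and 0 adjusted over the list alone), with a mean of -2.02 (camera adjusted p = 6.4e-14; adjusted p = 0.0616 with an estimated correlation). They included sucrase-isomaltase, Sis, at -2.95, the glucose transporter Slc5a1 at -2.52 and the amino acid transporter Slc7a9 at -2.09 (SE 0.25, adjusted p = 3.72e-05). In lipid absorption 15 of 24 fell and 0 rose (17 and 1 adjusted over the list alone; mean -1.46, adjusted p = 8.33e-10; adjusted p = 0.078 with an estimated correlation). Dgat1 was at -2.19 and Abcg5 at -2.93. In brush border structure 12 of 17 fell and 0 rose (15 and 0 adjusted over the list alone; mean -1.45, adjusted p = 1.15e-09; adjusted p = 0.0503 with an estimated correlation). There, Slc9a3r1 was at -1.74 and Ush1c at -1.79, with the opposite sign on its other probe, which was at background. In bile acid and xenobiotic metabolism 13 of 32 fell and 0 rose (16 and 0 adjusted over the list alone; mean -1.09, adjusted p = 2.86e-06; adjusted p = 0.0869 with an estimated correlation). These included both subunits of the bile acid exporter, Slc51a at -2.89 and Slc51b at -2.18.

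Secretory lists moved apart by camera. Paneth cell markers shifted by 1.17 (camera adjusted p = 0.00169; adjusted p = 0.241 with an estimated correlation), and 5 of 11 rose, also adjusted over the list alone. They were Defa31, Itln1 at 1.78, and Sox9 at 1.87, Mmp7 at 0.92 and Ephb3 at 0.72, the last 3 of which are also on the Wnt target list. Without control replicate 1 the list was at 0.77. Goblet cell markers shifted by -0.56 (adjusted p = 0.0195; adjusted p = 0.302 with an estimated correlation), with 5 of 19 falling and 0 rising, the same numbers as when adjusted over the list alone. Clca1 fell by 3.11 (SE 0.51, adjusted p = 0.000507) and Bcas1 fell by 2.40 (SE 0.24, adjusted p = 8.21e-06). Enteroendocrine markers shifted by -0.50 (adjusted p = 0.00163; adjusted p = 0.078 with an estimated correlation). There 7 of 24 fell, such as Cck at -2.10 and chromogranin A, Chga, at -1.49, and 1 rose, Neurog3 at 2.46 (11 and 1 adjusted over the list alone). In the tuft cell list 3 genes fell, Alox5ap at -0.95 and Plcg2 at -1.17 among them, and the mean was -0.31 (adjusted p = 0.14).

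Markers of T cells and intraepithelial lymphocytes shifted by -1.16 (camera adjusted p = 1.81e-06; adjusted p = 0.217 with an estimated correlation), with 9 of 19 falling and 0 rising (12 and 0 adjusted over the list alone). Among them were the T cell receptor kinase Zap70 at -2.43 (SE 0.32, adjusted p = 0.000103), Cd3e at -2.15, and Itgae, the integrin by which these cells hold on to epithelium, at -2.68. Smooth muscle markers shifted by -0.96 (adjusted p = 0.0195; adjusted p = 0.454 with an estimated correlation) with 1 of 13 falling, Mylk at -2.17 (2 adjusted over the list alone), and Tpm2 at -1.48 (0.0536). B cell markers averaged -0.19 (0.539), macrophage markers -0.25 (0.334) and fibroblast markers -0.42 (0.137). The list of interferon-stimulated genes and antigen presentation did not pass the test (mean 0.63, adjusted p = 0.221), and its members divided. Of the 29, 10 rose, Ifit2 at 3.37, Rsad2 at 2.95, Ifit3 at 2.65 and Oas2 at 2.64 (adjusted p = 0.0154) among them. The 4 that fell were all of MHC class II, H2-Aa at -1.87, Ciita at -1.51, H2-Ab1 at -1.24 and Cd74 at -0.96. The Notch list also divided, with 4 rising and 3 falling (mean 0.08, adjusted p = 0.573).

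Across all probes 3390 changed by limma, 1836 higher and 1554 lower, 2389 of them by more than 2-fold. With slide as a block 3391 changed, with 1952 within slide 1 and 204 within slide 2, where 1 Apc deficient array takes the spread of the other groups. Without Apc deficient replicate 2 the count was 2044. The means of the 15 lists that passed the test moved by at most 0.08 with slide as a block. Within slides 1 and 2 they were 0.76 and 0.83 for Wnt targets, 1.38 and 1.29 for stem cells, 1.45 and 1.41 for G1/S, 0.61 and 0.95 for G2/M and 1.16 and 1.37 for ribosome biogenesis. Values of 0.86 and 0.75 were found for reserve stem cells, 1.502 and 1.10 for Paneth, -0.55 and -0.51 for goblet and -0.45 and -0.57 for enteroendocrine cells. They were -1.96 and -2.07 for enterocyte digestion, -1.36 and -1.60 for lipid absorption, -1.38 and -1.52 for the brush border, -1.04 and -1.17 for xenobiotic metabolism. The other values were -0.88 and -1.46 for lymphocytes and -1.72 and -0.12 for smooth muscle. The smooth muscle call ended within slide 2 (adjusted p = 0.804), without control replicate 1 (-0.48, 0.183), the array rich in smooth muscle RNA, and without Apc deficient replicate 1 (0.0708). That of reserve stem cells ended within slide 2 (0.051), without Apc deficient replicate 2 (0.0537) and without control replicate 3 (0.0508), and that of goblet cells without Apc deficient replicate 2 (0.0613).

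With loss of Brg1 on top of Apc, lists of stem cell markers, Wnt targets, cell division and interferon-stimulated genes were lower by camera than with loss of Apc alone, and those of enterocytes and lymphocytes higher. Of 12 lists, 2, Wnt targets and stem cell markers, passed with an estimated correlation. Olfm4 fell from 11.61 ± 1.11 (SD, n = 3) in Apc deficient to 6.76 ± 0.41 (n = 4) in Brg1-Apc deficient mice, 28.8-fold (limma adjusted p = 2.84e-05). Lgr5 fell by 1.83 (SE 0.26, adjusted p = 0.000362) to 5.96 ± 0.24, beside 6.02 ± 0.17 in control. Olfm4 had the largest fall, followed by Oas2 at -4.06 (SE 0.69, adjusted p = 0.00174), Emp2 at -3.70, Gbp3 at -3.66 and Phf11d at -3.47. The largest rises were in Aldh4a1 at 3.38 (SE 0.41, 10.4-fold, adjusted p = 0.000124). Others were Slc26a6 at 3.32, Car4 at 3.31, Arg2 at 3.26 and Dbp at 3.25, with adjusted p up to 0.00614. These genes were chosen as before. The Brg1-Apc deficient means of Emp2, Nqo1 and Myc were at background, so the size of their falls is uncertain.

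Of 19 stem cell markers, 7 fell and 0 rose (11 and 0 adjusted over the list alone), with a mean of -1.06 (camera adjusted p = 4.41e-08; adjusted p = 0.0416 with an estimated correlation). Of 29 Wnt targets, 7 fell and 1 rose (9 and 1 adjusted over the list alone), with a mean of -0.50 (adjusted p = 6.4e-05; adjusted p = 0.0416 with an estimated correlation). Among the 7 were Tiam1 at -1.81 (SE 0.26, adjusted p = 0.000509), Sox9 at -1.50 (SE 0.30, adjusted p = 0.00613) and Myc at -1.93, and the 1 was Tgfbi at 1.30, which had fallen with loss of Apc. Of 26 G1/S genes, 5 fell and 0 rose (12 and 0 adjusted over the list alone; mean -0.79, adjusted p = 7.93e-09; adjusted p = 0.262 with an estimated correlation). Mcm3 was at -2.02 and Mcm10 at -1.37. Genes of G2/M shifted by -0.67 (adjusted p = 3.25e-05; adjusted p = 0.291 with an estimated correlation), with 2 of 27 falling, Ndc80 at -0.90 and Nusap1 at -1.18, and 9 adjusted over the list alone. Ribosome biogenesis shifted by -0.63 (adjusted p = 3.95e-05; adjusted p = 0.262 with an estimated correlation), with 3 of 24 falling, Ebna1bp2 at -1.27 and Nop56 at -2.15 among them, and 5 adjusted over the list alone. Paneth cell markers shifted by -1.07 (adjusted p = 0.00166; adjusted p = 0.32 with an estimated correlation), with 1 of 11 falling, Sox9, and 2 adjusted over the list alone. Defa31 was at -2.69 (SE 0.87, adjusted p = 0.0743). In the Notch list 5 of 23 fell and 0 rose, Hes1 at -1.70 and Dll1 at -0.99 among them, but the list did not pass the test (mean -0.40, adjusted p = 0.0501).

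Of 29 interferon-stimulated and antigen presentation genes, 12 fell and 1 rose, Zbp1 at 0.77 (19 and 1 adjusted over the list alone), with a mean of -1.43 (camera adjusted p = 3.81e-10; adjusted p = 0.262 with an estimated correlation). The fallen genes included Rsad2 at -3.06, Cxcl10, a chemokine that draws T cells, at -3.27, and Ifit3 at -2.48. In the same arrays T cell and intraepithelial lymphocyte markers shifted the other way, by 1.02 (adjusted p = 4.53e-07; adjusted p = 0.262 with an estimated correlation), with 9 of 19 rising and 0 falling (10 and 0 adjusted over the list alone). Zap70 rose by 1.73 (SE 0.32, adjusted p = 0.00349), Itgae by 2.34 and Ccl5 by 1.81. Macrophage markers averaged -0.27 (0.216) and B cell markers 0.04 (0.968). Of 22 enterocyte digestion genes, 10 rose and 0 fell (15 and 0 adjusted over the list alone), with a mean of 1.42 (adjusted p = 3.81e-10; adjusted p = 0.262 with an estimated correlation). Slc7a9 rose by 2.09 and Sis by 2.06. In lipid absorption 6 of 24 rose (9 up and 1 down adjusted over the list alone; mean 0.72, adjusted p = 0.000502; adjusted p = 0.358 with an estimated correlation), among them Mogat2 by 2.17 and Dgat1 by 1.85. In brush border structure 6 of 17 rose and 1 fell (7 and 1 adjusted over the list alone; mean 0.58, adjusted p = 0.00372; adjusted p = 0.34 with an estimated correlation). Cdhr2 was at 2.01. Xenobiotic metabolism shifted by 0.38 (adjusted p = 0.0465; adjusted p = 0.487 with an estimated correlation). It had 8 of 32 rising, Gsta1 by 2.47 (SE 0.28, adjusted p = 7.95e-05), and 2 falling, the same numbers as adjusted over the list alone. Nqo1 fell by 2.08 (SE 0.27, adjusted p = 0.000222), its other probe, at background, having the opposite sign. Goblet cell markers went both ways, Bcas1 at 1.45 and Slc12a8 at -1.67 (list mean 0.15, adjusted p = 0.661), and enteroendocrine and tuft cell lists averaged 0.04 (0.907) and 0.12 (0.771), with Sct at 1.18 (0.00742), Pcsk1 at 0.68 (0.0512), Plcg2 at 0.87 (0.103) and Avil at -0.70 (0.129).

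By limma 1844 probes changed, 825 higher and 1019 lower in Brg1-Apc deficient mice, and 1338 of them by more than 2-fold. With slide as a block 1834 changed, against 1792 within slide 1 and 2 within slide 2. Counts were 1112 without Apc deficient replicate 1, 610 without Apc deficient replicate 2, 1088 without Brg1-Apc deficient replicate 4 and 2944 without Brg1 deficient replicate 4, an array that enters this comparison only through the shared spread. The 12 list means moved by at most 0.07 with slide as a block. Within slides 1 and 2 they were -0.55 and -0.46 for Wnt targets, -1.25 and -0.78 for stem cells, -1.07 and -1.33 for Paneth cells. They were -0.84 and -0.68 for G1/S, -0.75 and -0.53 for G2/M, -0.63 and -0.62 for ribosome biogenesis, and -1.43 and -1.24 for interferon-stimulated genes and 1.18 and 0.88 for lymphocytes. They were 1.30 and 1.53 for enterocyte digestion, 0.54 and 0.93 for lipid absorption, 0.51 and 0.65 for the brush border and 0.27 and 0.52 for xenobiotic metabolism. The last 3 were not past the test within slide 1 (adjusted p = 0.0501, 0.0501 and 0.147). Without Apc deficient replicate 2, lipid absorption was at 0.46 and the brush border at 0.35. Xenobiotic metabolism was at 0.64 without Apc deficient replicate 1, and its call also ended without Brg1-Apc deficient replicate 1 (0.117) or 4 (0.25, 0.195), Apc deficient replicate 2 (0.15, 0.241) or 3 (0.127), or control replicate 1 (0.0524), 2 (0.0515) or 4 (0.0514).

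**Figure D3:**
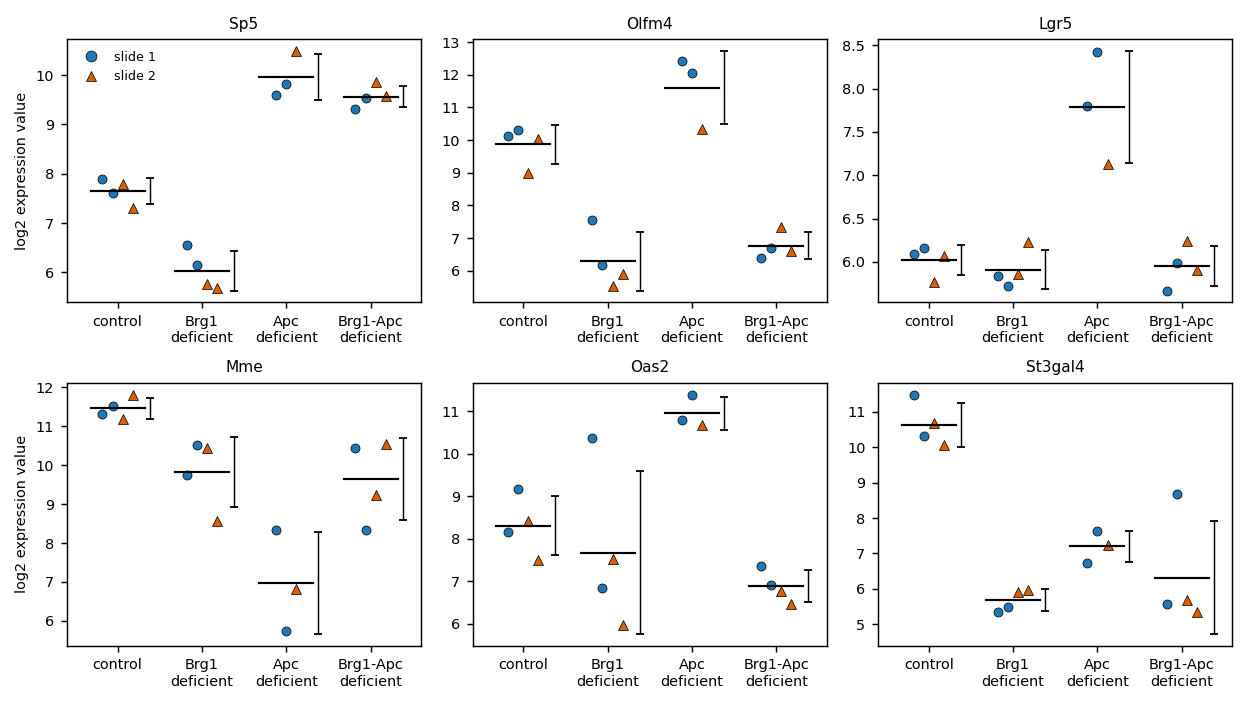
Log2 values of Sp5, Olfm4, Lgr5, Mme, Oas2 and St3gal4 (vertical axes) on each array by group, with circles for slide 1, triangles for slide 2, a line at the group mean and brackets of ± 1 SD. Sp5 averages 9.97 in Apc deficient and 9.57 in Brg1-Apc deficient mice, whereas Olfm4 averages 11.61 and 6.76.

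Whether the effect of one loss depended on the other was tested by the interaction, the Brg1 effect in mice without Apc minus the Brg1 effect in mice with Apc. Enterocyte genes lay on its positive side. The digestion list had a mean of 1.82 (camera adjusted p = 1.58e-14; adjusted p = 0.309 with an estimated correlation), with 5 of 22 genes above 0 past the test and 15 adjusted over the list alone. The peptidase genes Mme at 4.30 (SE 0.80, adjusted p = 0.0229) and Xpnpep2 at 4.27 (SE 0.77, adjusted p = 0.0197) were among the largest. Lipid absorption averaged 1.08 (adjusted p = 3.51e-07), brush border structure 0.99 (adjusted p = 2.32e-05) and xenobiotic metabolism 0.97 (adjusted p = 5.23e-05), with adjusted p = 0.318 with an estimated correlation in all 3. Past the test were 2 of 24, 1 of 17 and 4 of 32 genes (9, 4 and 8 adjusted over the list alone). T cell and intraepithelial lymphocyte markers averaged 1.08 (adjusted p = 3.51e-07; adjusted p = 0.343 with an estimated correlation), with 1 of 19 past the test, and 10 adjusted over the list alone. On the negative side were interferon-stimulated genes, with a mean of -1.12 (adjusted p = 4.82e-05; adjusted p = 0.559 with an estimated correlation). There, 1 of 29 was below 0 past the test, Ifit3 at -3.74 (SE 0.64, adjusted p = 0.0153), with 14 below and 4 above 0 adjusted over the list alone. Atg9b, at -2.85 (SE 0.35, adjusted p = 0.00299), and Ly6d, at -3.09 (SE 0.46, adjusted p = 0.00996), kept their calls whichever array was left out. Atg9b averaged 5.78 in control, 5.33 in Brg1 deficient, 10.56 in Apc deficient and 7.27 in Brg1-Apc deficient mice, so that where Apc was present it was at background and a fall with loss of Brg1 could not be measured in full.

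The list of stem cell markers had an interaction of -0.34 (camera adjusted p = 0.0234; adjusted p = 0.423 with an estimated correlation), with 1 of 19 past the test, Lgr5 (2 adjusted over the list alone). That of Wnt targets averaged -0.14 and did not pass (adjusted p = 0.158), with 2 of 29 below 0 past the test and Ascl2 at -1.42 (0.0775). Lgr5 had an interaction of -1.72 (SE 0.35, adjusted p = 0.03) and means of 6.02, 5.91, 7.79 and 5.96 in control, Brg1, Apc and Brg1-Apc deficient mice. All but the Apc deficient mean are close to background, where a smaller change could not be seen, so that its interaction depends on that limit. Lists of cell division did not pass this test, at -0.08 (0.443) for G1/S, whose median was above 0, -0.09 (0.549) for G2/M and -0.17 (0.299) for ribosome biogenesis. The stem cell value was -0.63 within slide 1 and 0.02 within slide 2 (adjusted p = 0.983), and its call ended without Brg1-Apc deficient replicate 1 (0.114), Apc deficient replicate 2 (0.0757), Brg1 deficient replicate 1 (0.104) or 2 (0.0743). The Lgr5 call ended without Brg1-Apc deficient replicate 1 (0.0647) or 4 (0.0759), Apc deficient replicate 1 (0.0513) or 2 (0.0958), control replicate 1 (0.0602), 3 (0.0679) or 4 (0.061), or Brg1 deficient replicate 1 (0.0506).

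In all, 225 probes had an interaction by limma, 164 above and 61 below 0, and all 225 exceeded 2-fold. The number was 234 with slide as a block and 111 within slide 1. Slide 2 holds a single Apc deficient array, so its own count cannot be weighed. The number moved with single arrays. It was 23 without Apc deficient replicate 2, 124 without replicate 3 of that group, 74 and 58 without Brg1-Apc deficient replicates 1 and 4. It was 74, 84 and 70 without control replicates 1, 3 and 4, 112 without Brg1 deficient replicate 1 and also without replicate 2, and 595 without Brg1 deficient replicate 4. Without Apc deficient replicate 2 the calls of Mme (adjusted p = 0.0849), Xpnpep2 (0.0807) and Ifit3 (0.068) ended, and that of Mme also without Brg1-Apc deficient replicate 1 (0.0502) or 4 (0.0549) or control replicate 4 (0.053). The 7 list means moved by at most 0.07 with slide as a block. Besides the stem cell list they were, within slides 1 and 2, 1.71 and 1.92 for enterocyte digestion, 0.92 and 1.27 for lipid absorption, 0.83 and 1.15 for the brush border. They were 0.93 and 1.04 for xenobiotic metabolism, 1.25 and 0.93 for lymphocytes and -1.34 and -0.73 for interferon-stimulated genes, which did not pass the test within slide 2 (adjusted p = 0.0827).

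Across 16592 genes, the change with loss of Apc where Brg1 was lost followed the change where Brg1 was present with a slope of 0.48 (jackknife SE 0.14) after the noise of the horizontal values was removed. Pearson's r was 0.579 and Spearman's rho 0.452, and 63.3% of genes had the same sign; genes are not independent replicates, so no p is given. The comparisons share no array but share each probe's spread, so expectations for independent lists may be too low. Of the 1836 probes higher with Apc loss in the presence of Brg1, 817 were also higher in its absence (81.7 expected). Of the 1554 lower ones 143 were also lower (14.5). In the other direction, the change with loss of Brg1 where Apc was lost followed that where Apc was present with a slope of 0.77 (SE 0.26), r of 0.418 and rho of 0.355, and 62.3% of genes had the same sign. There, 90 probes were higher in both (5.65 expected) and 167 lower (21.6). Within slide 2 this second slope was 0.32.

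**Figure D4:**
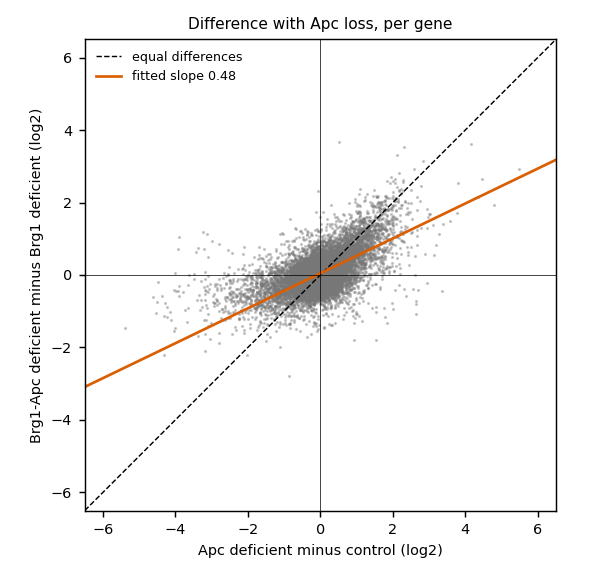
Each point is 1 of 16592 genes, with the log2 difference Apc deficient minus control on the horizontal axis and Brg1-Apc deficient minus Brg1 deficient on the vertical axis. The dashed line marks equal changes and the orange line the fitted slope of 0.48.

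Against control, mice that had lost both genes had higher Wnt target, stem cell, G1/S and ribosome biogenesis lists and lower enterocyte lists, while the G2/M list did not pass the test, and 0 of 16 lists passed with an estimated correlation. Sp5 rose by 1.92 (adjusted p = 0.0002) and Prox1 by 1.59, whereas Olfm4 fell by 3.11 (adjusted p = 0.000662). The largest rises were in Slc40a1 at 3.77 (SE 0.48, 13.6-fold, adjusted p = 0.00024), Krt23 at 3.33 (SE 0.28, adjusted p = 7.52e-06) and Mpst at 3.01. The largest falls were in St3gal4 at -4.32 (SE 0.55, adjusted p = 0.000214), Cyp3a25 at -4.05 and Adh1 at -3.99. The groups did not overlap in these 6 genes. Of the Wnt targets 5 of 29 rose and 2 fell, Tgfbi and Kremen1 (7 and 2 adjusted over the list alone; mean 0.29, camera adjusted p = 0.0163), and of the stem cell markers 4 of 19 rose and 1, Olfm4, fell (6 and 1 adjusted over the list alone; mean 0.32, adjusted p = 0.0173). In G1/S 10 of 26 rose (11 adjusted over the list alone; mean 0.67, adjusted p = 6.36e-07) and in ribosome biogenesis 7 of 24 (11 adjusted over the list alone; mean 0.64, adjusted p = 5.94e-06). Each of these 4 lists had adjusted p = 0.293 with an estimated correlation, and so had the lists of the next sentences where no other value is given. Falls were found in 6 of 24 genes of lipid absorption (mean -0.75, adjusted p = 7.75e-06), 2 of 17 of the brush border (-0.87, 1.88e-05) and 7 of 32 of xenobiotic metabolism, where 2 rose (-0.71, 0.000892), with 8, 6 and 9 falling when adjusted over the list alone. Of the enterocyte digestion genes 3 of 22 fell (4 adjusted over the list alone; mean -0.60, adjusted p = 0.000711; adjusted p = 0.369 with an estimated correlation). In the goblet list 4 of 19 fell and 1 rose (7 and 1 adjusted over the list alone; mean -0.41, adjusted p = 0.00945). In the enteroendocrine list 7 of 24 fell, Cck by 2.10 among them, and 1, Neurog3, rose (8 and 1 adjusted over the list alone; mean -0.45, adjusted p = 0.000461). Interferon and antigen presentation genes shifted by -0.80 (adjusted p = 6.36e-07), with 9 of 29 falling (13 adjusted over the list alone), Ciita, Tap1 and Igtp among them.

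Lists of other cell types were lower too by camera. In these lists the falling genes numbered 1 of 18 for macrophages (mean -0.52, camera adjusted p = 0.0025), 1 of 18 for fibroblasts (-0.78, 0.000352), 0 of 13 for smooth muscle (-1.13, 0.000892), 0 of 13 for endothelium (-0.58, 0.00945) and 0 of 10 for acinar cells (-0.95, 0.021). When adjusted over the list alone, 4, 4, 4 and 3 fell in the first 4. With an estimated correlation, the first 3 had an adjusted p = 0.293, endothelium had adjusted p = 0.473 and acinar cells had adjusted p = 0.659. Without control replicate 1, the array rich in smooth muscle RNA, that list was at -0.65 (0.0161). The acinar value rested on control replicate 4, the array with pancreatic RNA. It was 0.12 without it (adjusted p = 0.719), 0.21 within slide 1 and -2.10 within slide 2, where that array lies, and its call also ended without Brg1-Apc deficient replicate 4 (0.05). Lists of G2/M, at 0.14 (0.313), the Notch pathway, at -0.32 (0.162) with a median above 0, Paneth cells, at 0.10 (0.448) with a median below 0, and lymphocytes, at -0.14 (0.441), did not pass the test.

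By limma 1569 probes differed between these mice and control, 761 higher and 808 lower, 994 of them by more than 2-fold. With slide as a block 1765 did, with 693 within slide 1 and 10 within slide 2. The count was 1010, 1044 and 955 without control replicates 1, 3 and 4, 975 and 959 without Brg1-Apc deficient replicates 2 and 3, and 2697 without Brg1 deficient replicate 4. The 16 list means moved by 0.00 at most with slide as a block. Within slides 1 and 2 they were 0.20 and 0.37 for Wnt targets, 0.13 and 0.51 for stem cells, 0.61 and 0.74 for G1/S, 0.53 and 0.74 for ribosome biogenesis. The values were -0.47 and -0.34 for goblet and -0.48 and -0.42 for enteroendocrine cells, -0.65 and -0.54 for enterocyte digestion and -0.82 and -0.68 for lipid absorption. They were -0.87 and -0.87 for the brush border, -0.77 and -0.66 for xenobiotic metabolism, -0.74 and -0.85 for interferon-stimulated genes. Those of other cell types were -0.50 and -0.54 for macrophages, -0.99 and -0.56 for fibroblasts, -1.73 and -0.53 for smooth muscle and -0.75 and -0.41 for endothelium. The Wnt and stem cell calls ended within slide 1 (adjusted p = 0.125 and 0.332) and without Brg1-Apc deficient replicate 3 (0.0588 and 0.0851), and those of fibroblasts and endothelium within slide 2 (0.0562 and 0.0917).

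Where Brg1 was lost, lists of Wnt targets, stem cell markers and cell division were higher with loss of Apc by camera. Sp5 rose by 3.53 (SE 0.24, 11.6-fold, limma adjusted p = 1.07e-06), Krt23 by 3.60 (SE 0.28, adjusted p = 4.7e-06) and Cdca7 by 3.32 (SE 0.38, adjusted p = 0.000107), the 3 largest rises. Slc6a4 fell by 2.11 (SE 0.28, adjusted p = 0.000349) and Upk3b by 1.70 (SE 0.20, adjusted p = 0.000107). Acta1 fell by 1.80 (adjusted p = 0.0362). Its call ended without any 1 Brg1-Apc deficient array or Brg1 deficient replicate 1 or 3 (adjusted p from 0.0707 to 0.12). Of 19 stem cell markers 9 rose and 0 fell, also adjusted over the list alone (mean 1.03, camera adjusted p = 3.41e-07), and of 29 Wnt targets 9 rose and 0 fell (10 and 1 adjusted over the list alone; mean 0.64, adjusted p = 5.03e-05). In G1/S 18 of 26 rose (21 up and 1 down adjusted over the list alone; mean 1.38, adjusted p = 1.93e-19) and in ribosome biogenesis 12 of 24 (16 adjusted over the list alone; mean 1.10, adjusted p = 1.59e-12). These 4 lists kept their calls, with adjusted p = 0.0427 with an estimated correlation. In G2/M 10 of 27 rose (13 adjusted over the list alone; mean 0.72, adjusted p = 5.93e-06; adjusted p = 0.259 with an estimated correlation). Of the genes of brush border structure 3 of 17 fell (mean -0.46, adjusted p = 0.00222; adjusted p = 0.312 with an estimated correlation). Lipid absorption shifted by -0.39 with 0 of 24 past the test (adjusted p = 0.00572; adjusted p = 0.412 with an estimated correlation), while enterocyte digestion averaged -0.20 and did not pass (adjusted p = 0.0616). Enteroendocrine markers shifted by -0.32 with 2 of 24 falling and 1 rising (5 and 1 adjusted over the list alone; adjusted p = 0.00218; adjusted p = 0.111 with an estimated correlation). Interferon and antigen presentation genes shifted by -0.50 with 2 of 29 falling (adjusted p = 0.00222; adjusted p = 0.449 with an estimated correlation). Macrophage markers shifted by -0.42 with 0 of 18 past the test (adjusted p = 0.00222; adjusted p = 0.259 with an estimated correlation) and fibroblast markers by -0.54 with 0 of 18 (adjusted p = 0.00757; adjusted p = 0.412 with an estimated correlation). Lymphocyte markers averaged -0.08 (0.52).

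The Paneth cell list shifted by 0.84 with 3 of 11 rising (adjusted p = 0.0118; adjusted p = 0.407 with an estimated correlation). It was -0.33 within slide 1 (0.949) and 2.01 within slide 2, and its call ended without Brg1 deficient replicate 3 (0.52, 0.0786) or 4 (0.55, 0.133), while it was 1.28 without replicate 1. Cholesterol synthesis shifted by 0.34 with 1 of 17 rising (adjusted p = 0.0482; adjusted p = 0.516 with an estimated correlation). It was -0.06 within slide 1 (0.72) and 0.73 within slide 2, and missed the threshold with slide as a block (0.0549). It was 0.01 without Brg1 deficient replicate 4 (0.896) and 0.52 without replicate 2, and its call also ended without Brg1 deficient replicate 3 (0.0542), Brg1-Apc deficient replicate 1 (0.112) or 2 (0.0812), Apc deficient replicate 1 (0.0516) or control replicate 1 (0.0508). Goblet cell markers, at -0.24 with 0 of 19 past the test (adjusted p = 0.042; adjusted p = 0.411 with an estimated correlation), were not past the test within slide 1 (-0.30, 0.0545) or slide 2 (-0.18, 0.197), nor without Brg1-Apc deficient replicate 1 (0.112) or 2 (0.121) or Brg1 deficient replicate 1 (0.0907), 3 (0.094) or 4 (0.0753). The calls of lipid absorption without Brg1-Apc deficient replicate 2 (-0.25, 0.0669), of interferon genes without Brg1 deficient replicate 1 (-0.18, 0.155; -0.76 without replicate 4) and of fibroblasts without Brg1 deficient replicate 2 (0.0664) or 4 (0.0641) ended as well.

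By limma 1384 probes changed between mice without both genes and mice without Brg1 alone, 1144 higher and 240 lower, 870 of them by more than 2-fold. Quantile scaling gave 896 higher and 383 lower. With slide as a block 1478 changed, with 762 within slide 1, 379 higher and 383 lower, and 293 within slide 2, 283 higher and 10 lower. The count was 897 without Brg1-Apc deficient replicate 3 and 921 without Brg1 deficient replicate 3. Without Brg1 deficient replicate 4 it was 2399, with 1324 higher and 1075 lower. The 14 list means moved by 0.00 at most with slide as a block. Within slides 1 and 2 they were 0.49 and 0.80 for Wnt targets, 0.75 and 1.31 for stem cells, 1 and 1.76 for G1/S, 0.35 and 1.08 for G2/M and 0.80 and 1.40 for ribosome biogenesis. They were -0.52 and -0.11 for enteroendocrine cells, -0.44 and -0.34 for lipid absorption, -0.55 and -0.38 for the brush border. They were -0.65 and -0.34 for interferon genes, -0.55 and -0.29 for macrophages and -0.50 and -0.58 for fibroblasts. Not past the test within slide 2 were enteroendocrine cells (0.207), lipid absorption (0.0506) and macrophages (0.0893).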

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

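Tests of normalization, labels, compression, other cell types, escape and crypt share, and permutations of list means and of residuals, were chosen after the results were seen, while the interaction, slides, single arrays left out and other splits of the arrays were planned. Dixon's test picks out about 1 in 20 groups by chance. It picked out 2 of 105 groups of list means, 16 of 309 groups of gene values and 1 of 9 groups of array measures.

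Brg1 deficient replicate 4 stood apart from its group, with the narrowest range of signal. Smarca4 was -0.99 relative to the lowest array with Brg1, and the mean of the Wnt and G1/S lists was -1.08 relative to the lowest Brg1-Apc deficient array. These values argue against a wrong label but do not exclude it, since a compressed signal could lower both. Smarca4 also does not tell Brg1 deficient from Brg1-Apc deficient mice. RNA of another cell type stays open, because lymphocyte markers exceeded those of the other 3 arrays by 0.96 after quantile normalization, against an SD of 0.23. Compression of the signal stays open too, because residuals around a smooth curve through the other arrays of its group had an SD of 0.746, against at most 0.555 on the other 14 arrays, but an MAD of 0.471 against at most 0.465. No biological explanation was tested.

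The list of interferon-stimulated genes was higher in Apc deficient than in Brg1-Apc deficient arrays by camera (adjusted p = 0.262 with an estimated correlation). The 12 genes that fell averaged 9.53, 10.33 and 9.25 on the Apc deficient and 6.74 to 7.68 on the Brg1-Apc deficient arrays, with 9.40 on Brg1 deficient replicate 1. Quantile normalization kept 95.4% of the difference, which argues against the authors' normalization as the whole cause. T cell and intraepithelial lymphocyte markers moved the other way by 1.02 (adjusted p = 0.262 with an estimated correlation). This argues against more such cells in the Apc deficient scrapes. Macrophage (-0.27, camera adjusted p = 0.216) and B cell markers (0.04, 0.968) leave other immune cells open. Slide position cannot be told apart from genotype, and an effect of Brg1 on these genes stays open as well.

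Enterocyte and lymphocyte markers were lost less in Brg1-Apc deficient than in Apc deficient arrays by camera (adjusted p = 0.262 for both lists with an estimated correlation). Quantile normalization kept 105% of the difference. Cells that escaped recombination at both genes, returning 50% of the Smarca4 gap (0.68), were excluded (upper bound 0.24 against Brg1 deficient mice). Less escape, or escape at Apc alone, stays open. A smaller share of crypt tissue stays open, since the share of the Apc change that was left ran from 12% to 60% over 7 crypt and villus lists, with a gap of -30.5 points (SE 8.19) between enterocyte digestion and brush border, so that their means decide nothing. An effect of Brg1 on these genes stays open, as does slide position.

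In all 5 comparisons of groups only the real split, 1 of 35, gave as many changed probes. Other splits mix the group effect into the spread, so this argues against chance without excluding it. The real counts and the highest of the other splits were 721 and 21 for Brg1 deficient, 3390 and 4 for Apc deficient and 1569 and 1 for Brg1-Apc deficient against control. They were 1844 and 185 against Apc deficient and 1384 and 634 against Brg1 deficient mice. For the interaction, with 225 probes, 3 of 100 splits gave as many (highest other 407), but these mix both losses into the spread. When residuals of the model without an interaction were permuted, only the real arrangement, 1 of 100, gave as many, the highest other being 3. This argues against chance without excluding it, as arrays differ in spread and the count fell to 23 without Apc deficient replicate 2. Chance is not excluded for the 70 list calls either, since 15 of 100 splits gave as many (median of the others 49, highest 87). In exact permutation tests of the list means the smallest p possible, 0.0286, is too high for a few lists to pass after adjustment over 35. Against control 3 of 6 camera calls reached it in Brg1, 13 of 15 in Apc and 10 of 16 in Brg1-Apc deficient mice. In Brg1-Apc against Apc and Brg1 deficient mice 8 of 12 and 6 of 14 did. In Brg1 deficient mice G1/S (0.0571), ribosome biogenesis (0.0857) and G2/M (0.143) missed it. There, lipid absorption, xenobiotic metabolism and SWI/SNF, not called, reached it.

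Single arrays far from their group were also found for list means and for correlation. Endothelial markers were 5.536 on control replicate 3, and acinar markers 10.388 on control replicate 4. Brg1-Apc deficient replicate 2 had a mean correlation of 0.954 with its group. For genes, control replicate 2 stood apart for Defa31 (6.893) and control replicate 3 for Ly6d (7.056) and Acta1 (8.267). Brg1 deficient replicate 2 stood apart for Klk1 (6.927), replicate 3 for Slc12a2 (8.490) and Aldh4a1 (13.943), and replicate 4 for Adh1 (10.230), Enpp7 (6.442) and Car4 (9.625). Brg1-Apc deficient replicate 2 did so for St3gal4 (8.694), Msx1 (9.530) and Slc40a1 (9.813), and replicate 4 for Prc1 (10.454), Enpp7 (9.419), Phf11d (6.463) and Mcm3 (6.364).

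The interaction test in limma passed for 29 named genes, with adjusted p from 0.00299 to 0.0469. Of these, 6 had a group mean at background, no higher than 5.90, namely Atg9b, Cyp3a25, Myc, Slc15a1, St3gal4 and Upk3b. St3gal4, Cyp3a25 and Nat8 averaged 10.64, 10.15 and 10.52 in control mice and 5.39 to 7.20 in the other groups. Where either loss alone brings a gene near background a positive interaction follows, so these 3 values do not show that one loss changed the effect of the other. Single-array values for the interaction were computed only for the genes named under it. Among metabolic and transport genes the interaction was 4.080 for St3gal4, 4.624 for Cyp3a25, 4.118 for Nat8, 4.410 for Treh, 2.709 for Slc15a1, 3.480 for Slc7a8, 1.520 for Slc7a9 and 1.853 for Dgat1. It was 2.583 for Slc51a, 2.350 for Mogat2, 2.790 for Aldh4a1, 3.058 for Slc26a6, 3.336 for Arg2, 3.751 for Naaladl1, 4.299 for Mme and 4.266 for Xpnpep2. Other positive values were 1.835 for Nrarp, 1.794 for Bcas1, 2.206 for Zap70 and 2.334 for Mylk. Negative values were -2.854 for Atg9b, -2.198 for Rgcc, -2.943 for Phf11d, -1.718 for Lgr5, -3.737 for Ifit3, -3.094 for Ly6d, -2.615 for Cldn2, -1.968 for Myc and -1.339 for Upk3b. Without Apc deficient replicate 2 the calls of Cyp3a25, Treh, Nat8, Mme, Xpnpep2, Ifit3, Phf11d, Cldn2, Lgr5 and Myc ended (adjusted p from 0.068 to 0.141). Those of Lgr5 and Mme that ended without other arrays are given in the results. The Cyp3a25 call also ended without Brg1-Apc deficient replicate 1 or 4, Apc deficient replicate 3, Brg1 deficient replicate 2 or control replicate 1, 3 or 4 (0.0533 to 0.0662), and that of Treh without the same arrays, Brg1 deficient replicate 1 or control replicate 2 (0.0509 to 0.0817). That of Nat8 ended without Brg1-Apc deficient replicate 1 or 4, Brg1 deficient replicate 1 or 2 or control replicate 1 or 4 (0.0508 to 0.061). That of Phf11d ended without Brg1-Apc deficient replicate 1, 3 or 4, Apc deficient replicate 3 or control replicate 1, 3 or 4 (0.0565 to 0.0942). That of Cldn2 ended without Brg1-Apc deficient replicate 1, Apc deficient replicate 1 or 3, Brg1 deficient replicate 1 or 2 or control replicate 1, 3 or 4 (0.0513 to 0.0784). That of Myc ended without any 1 control array, Brg1-Apc deficient replicate 1, 3 or 4, Apc deficient replicate 1 or Brg1 deficient replicate 1 or 2 (0.0585 to 0.0883).

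Among lists the interaction test (camera) passed for stem cell markers (-0.345), enterocyte digestion (1.820), lipid absorption (1.080), brush border structure (0.989), xenobiotic metabolism (0.969), interferon-stimulated genes (-1.120) and lymphocyte markers (1.080). With an estimated correlation 0 of these 7 held, with adjusted p from 0.309 to 0.559. The stem cell value was 0.024 within slide 2, and its losses without single arrays and its limit by background are given in the results.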

How the results depend on the processing

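All alternatives were chosen before the data were examined, except the 13 arrays below. Where no reason is given the cause was not tested. Changed probes within slide 1 numbered 160 in Brg1 deficient, 1952 in Apc deficient and 693 in Brg1-Apc deficient against control, 762 in Brg1-Apc against Brg1 deficient mice and 111 in the interaction, and within slide 2 they numbered 60, 204, 10, 293 and 0, with 2 in Brg1-Apc against Apc deficient mice. These fits have fewer arrays. For the 0, limma gave 1702 probes at an unadjusted p under 0.05. With only the groups compared, 387 probes changed in Brg1 deficient and 2812 in Brg1-Apc deficient against control and 581 in Brg1-Apc against Brg1 deficient mice. Array weights gave 3022 in Brg1-Apc against Apc deficient mice, 2979 against control and 549 in the interaction. On the 13 arrays chosen after seeing the data the counts were 964, 4652 and 2014 against control in the order above, 2541 and 2001 in Brg1-Apc against Apc and Brg1 deficient mice and 762 in the interaction. With the replicate block, which also takes up slide, they were 763, 3188, 1678, 1618, 1361 and 212 in the same order. Leaving out each array gave 361 to 1143, 2044 to 4327, 955 to 2697, 610 to 2944, 897 to 2399 and 23 to 595. Arrays that moved a count by over 1.5 times are named in the results, and the 4327 was without Brg1 deficient replicate 4. The replicate numbers do not pair the samples. Of 21 pairs with the same number, 8 correlated above 0.1 after group means were removed, with a mean r of 0.0554 against -0.0175 in the other 63. Of 70 list calls, 8 held with an estimated correlation. For Wnt targets in Brg1 deficient against control mice, at -0.358, the call ended at -0.286 within slide 1, -0.431 with centred arrays, -0.575 with bright probes, -0.349 with the most variable probe and -0.358 with an estimated correlation, with adjusted p from 0.0556 to 0.389. Leaving out each array gave -0.404 to -0.296. Stem cell markers there were -0.712 with an estimated correlation (adjusted p = 0.389). Their interaction, at -0.345, turned to 0.024 within slide 2 and lost its call at -0.343 with quantile normalization and -0.345 with an estimated correlation and with fry, with adjusted p from 0.0739 to 0.983. Leaving out each array gave -0.460 to -0.255. The Brg1 slope of 0.77 was 0.323 within slide 2. Signs turned in Brg1-Apc deficient mice for acinar markers against control, at 0.211 within slide 1 and from -1.338 to 0.124 over single arrays, the highest without control replicate 4. Against Brg1 deficient mice they turned within slide 1 for Paneth markers (-0.329), cholesterol synthesis (-0.058) and lymphocyte markers (0.369), and in the interaction within slide 2 for Paneth markers (0.918). Of 120 calls of named genes, 27 held in every alternative run and 93 ended in at least 1. Of the 70 list calls 28 ended with the estimated correlation alone. With 1 array left out, 2959 list values kept their direction and side of the threshold, 39 lost and 54 gained a call, and with other alternatives 2391 did, 128 lost and 69 gained one. A pseudocount was not varied because the values are log2, the robust prior was not run for lists, which camera does not offer, and the interaction cannot be fitted on 2 groups. Weak probes near background limit small differences, and with only probes above the median level 993, 3778, 2041, 2311, 1688 and 328 probes changed.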

Other observations

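The clock genes, the genes set side by side here and the tests of secretory fates were chosen after the data were seen. Of 18 genes of the circadian clock and its output, 6 fell, 0 rose and 12 did not pass the test with loss of Apc. Dbp averaged 10.31 ± 1.40 in control, 10.03 ± 0.98 in Brg1 deficient, 6.34 ± 0.32 in Apc deficient and 9.59 ± 0.99 in Brg1-Apc deficient mice (SD). Dbp fell by 3.97 (SE 0.66, limma adjusted p = 0.000564), with Usp2 at -2.13 and Nr1d1 at -1.74, and these 3 passed whichever array was left out. The call of Tef, at -1.64, ended without Apc deficient replicate 2 (0.0933). Those of Cry2, at -1.01, and Per2, at -1.39, ended without any 1 Apc deficient array or control replicate 2 or 4, and that of Per2 also without control replicate 1, Brg1-Apc deficient replicate 1 or 3 or Brg1 deficient replicate 3 (adjusted p from 0.0539 to 0.16). In Brg1-Apc against Apc deficient mice Dbp was at 3.25 (adjusted p = 0.00614), Arntl at -0.92 (0.0413) and 16 did not pass. The Arntl call ended without any 1 Apc deficient array, control replicate 1, 2 or 4 or Brg1-Apc deficient replicate 1, 2 or 4 (0.0505 to 0.142). In Brg1 deficient mice Usp2 was at -2.22 and Bhlhe40 at -1.38 (0.015), a call that ended without control replicate 2 (0.0617) or 4 (0.0625) or Brg1 deficient replicate 3 (0.0623). Control replicate 3 had the lowest control values of Dbp, 8.26 against 10.59 to 11.32, and of Per2, 8.98 against 10.16 to 11.15, and without it 7 genes fell in Apc deficient and 5 in Brg1 deficient mice. The time of day of collection is not given in the sources used here.

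Adh1, low in all 3 groups with Cre, averaged 11.96 in control and 7.90, 8.76 and 7.97 in Brg1, Apc and Brg1-Apc deficient mice. On control replicate 4 the acinar genes Clps, Cela2a and Try4 reached 11.81, 11.61 and 10.87, and on control replicate 1 the smooth muscle genes Acta2, Des and Myh11 reached 13.04, 10.60 and 10.44.

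In Brg1 deficient mice 5 of 23 Notch pathway genes fell. Their list passed by camera (adjusted p = 0.037) but not with an estimated correlation (0.389) or in some settings given above. From these genes a shift of cells to secretory fates was tested as a hypothesis. Goblet, Paneth, enteroendocrine and tuft cell lists averaged -0.17, -0.74, -0.14 and -0.12 (jackknife SE 0.11, 0.78, 0.13 and 0.20). For goblet, enteroendocrine and tuft cells the highest mean plus 2 SE was 0.28, which excludes a rise of 0.5 in these lists. For Paneth cells it was 0.82, so that a shift to that fate stays open.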
